A study of Danio rerio with 32 samples.

How the data were processed

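Gene expression was measured on 32 dual-channel Agilent zebrafish arrays, 4 for each of 8 groups (BAA, DBT, PYR and DMSO at 24 and 48 hpf). Per the labels, each vial held 40 embryos of a wild type line in 4 ml, exposed to 25 μM compound or 1% DMSO from 6 hpf, and 1.2 μg of total RNA was labelled, the sample with Cy3 and a pooled reference of DMSO embryos of 24 and 48 hpf with Cy5. Groups and replicate numbers were taken from the labels.

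Per the file headers, the authors' scanner files hold spot intensity for both dyes, from Agilent Feature Extraction 10.7.3.1 with the protocol GE2_107_Sep09 and probes placed on the Zv8 (danRer6) build. Those files also hold, as the software wrote them for the authors, log10 ratios of Cy5 over Cy3 processed signals, used only to check the value table. The spot mean intensity and the median intensity of the local background were used, without the dye normalization and detrending of that software. The deposited value table holds log2 ratios, but its scale, centring and direction are not stated by the authors; from the values, each column is the log2 of Cy3 over Cy5 of the processed signals, and its column medians ran from -0.19 to -0.03. Of its 32 columns, 30 matched their own scanner file best (correlation of at least 0.99996), and the columns of PYR replicates 3 and 4 at 24 hpf matched each other's file, so the 2 are interchanged; as both belong to 1 group, no group value changes. The table holds 60 control spots among its probes.

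From the intensities, background was corrected by limma's normexp method with an offset of 50, and log2 Cy3 over Cy5 was normalised within each array by loess, with control spots given no weight. Spots that the software marked as outliers were set to missing, and spots of the same probe were averaged, which took 43803 spots to 43603 probes. A probe was tested when its Cy3 spot was well above background on at least 4 of the 32 arrays, which left 35023 probes, of which 20302 had exactly 1 gene symbol, for 13990 genes. Probes were named by the RefSeq accession in the files (17910), the gene name (2803), an Ensembl symbol (91) or the file's own name alone (1066); 32 had several symbols and 21701 none. Reference tables of a later genome assembly gave current symbols only, and coordinates are those in the files. For genes with several probes (4910) the brightest was used.

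Groups were compared with limma on all 32 arrays (8 group means, 24 residual degrees of freedom, a median of 32.1 in total after empirical Bayes moderation). Tests were two-sided, p was adjusted by the method of Benjamini and Hochberg within each comparison, and an adjusted p under 0.05 counts as changed. Intervals are at 95%. Each compound was compared with DMSO and with the other compounds at the same age, the effects at 48 and 24 hpf were compared by interaction terms, and DMSO embryos were compared between ages. A fold is given only when the probe was well above background in both groups, and as a lower bound when 1 group was not.

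The genes named for a comparison with DMSO were the 10 largest rises and 10 largest falls among changed genes whose 4 treated values all lay beyond all 4 DMSO values. Comparisons of compounds, interactions and the DMSO ages took 5 in each direction. The AHR panel (cyp1a, cyp1b1, cyp1c1, cyp1c2, ahrra, ahrrb and tiparp) and up to 4 changed members of each list were added. The comparisons, this rule, the settings and 24 gene lists, with at least 5 measured members each, were fixed before the data were examined. The lists were AHR-responsive genes, NRF2 and glutathione antioxidant genes, other xenobiotic metabolism genes, heat shock and unfolded protein response genes, p53 and DNA damage genes, cell cycle and replication genes, cholesterol biosynthesis genes, fatty acid and lipid handling genes, glycolysis and hypoxia genes, retinoid pathway genes, immediate early and inflammation genes, myeloid leukocyte markers, skeletal muscle genes, cardiac genes, vascular endothelial genes, erythroid genes, neural genes, lens and retina genes, pigment cell genes, hatching gland genes, liver and yolk syncytial layer genes, epidermis and ionocyte genes, cartilage, bone and matrix genes, and circadian clock genes. 1 member of the cholesterol list stayed in the list tests but is not reported here. In more than 1 list stand nqo1, mttp, npsn, mmp13a and klf2a. Lists were tested with camera of limma at a preset correlation of 0.01 and again with an estimated correlation, and adjusted over the 24 lists of a comparison.

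Correlations of log2 fold changes between compounds were compared with 200 data sets simulated without any effect and with values after splitting the DMSO arrays between the compounds. The arrays lay on 8 slides scanned on 2 days, with replicates 1 and 2 of each group on 1 day and replicates 3 and 4 on the other. Among arrays of the same age, BAA shared slides with DMSO and DBT with PYR, whereas neither DBT nor PYR shared a slide with DMSO. The correlation of arrays within slides was estimated at -0.0750. In no comparison did all 4 pairs of equal replicate number correlate above 0.1 after removal of group means, so samples sharing only a number were not treated as paired; a replicate block was run as an alternative.

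Alternatives were scaling of the average intensity between arrays (Aquantile), the processed signals, the Cy3 channel alone, the authors' table, no filter, a filter on all 32 arrays (26592 probes), outlier spots kept, slide as a random or fixed block, a replicate block, a moderated variance with intensity trend, array weights (0.124 to 3.41, lowest on the bright array), a fold of at least 1.5, only the groups compared in the fit, the mean of a gene's probes, and each array left out. A fit without the bright array (DBT replicate 4 at 48 hpf), scan day as a fixed block and lists with each array left out were chosen after seeing the data.

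The bright array had 43784 spots above background in Cy3 and 43773 in Cy5, against 28560 to 34794 and 22292 to 27974 on the other 31. Its median intensity was 983 in Cy3 and 1572 in Cy5, against 141 to 247 and 212 to 301, and 2913 of its spots were marked as outliers, against 16 to 878. The leading principal component of all arrays held 64.9% of the variance and the next 7.04%. No 2 replicates were copies, as the SD of their difference was at least 0.222.

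The fit was tested on simulated data (35023 probes, BAA and DMSO at 24 hpf). Of 50 probes changed at each size, 18 (36%) were called at 1.5-fold, 47 (94%) at 2-fold, 50 at 3-fold and 50 at 4-fold. Of 171 calls 6 (3.51%) were false, and the 5 contrasts without a change gave 0 calls with limma. Of 200 random lists, 3% had p under 0.05 with camera. These rates need not hold for real arrays. 2 unrelated effects correlated at 0.506 with shared DMSO arrays and 0.0032 with split ones. Software was R 4.3.3 (limma 3.58.1, statmod 1.5.0) and Python 3.11.15 (pandas 2.3.3, matplotlib 3.10.9).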

Results

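Whole zebrafish embryos were exposed in batches of 40 to 1 of 3 polycyclic aromatic hydrocarbons (PAHs) at 25 μM, or to the solvent dimethyl sulfoxide (DMSO, 1%) alone. Exposure began at 6 hours post fertilization (hpf), and embryos were collected at 24 or 48 hpf. The PAHs were benz[a]anthracene (BAA), whose fused rings form an angular array, dibenzothiophene (DBT), in which a sulfur-containing ring joins the benzene rings, and pyrene (PYR), a compact pericondensed ring system. Each of the 8 groups held 4 arrays, described in the labels as independent biological replicates, and 32 arrays were used. On every array the sample RNA was read against a pooled reference from DMSO embryos of both ages, so all values are log2 ratios of sample over reference. On 31 arrays between 28560 and 34794 of 43803 spots were well above background in the sample channel, and the median sample intensity was 141 to 247. On DBT replicate 4 at 48 hpf, 43784 spots were above background and the median intensity was 983. Of 43603 distinct probes, 35023 were tested. The precision of every comparison is limited by the number of arrays. The series title asks how PAHs of distinct structure differ in the transcripts they change, and the comparisons below set each compound against DMSO and against the other compounds at the same dose and age.

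**Figure D1:**
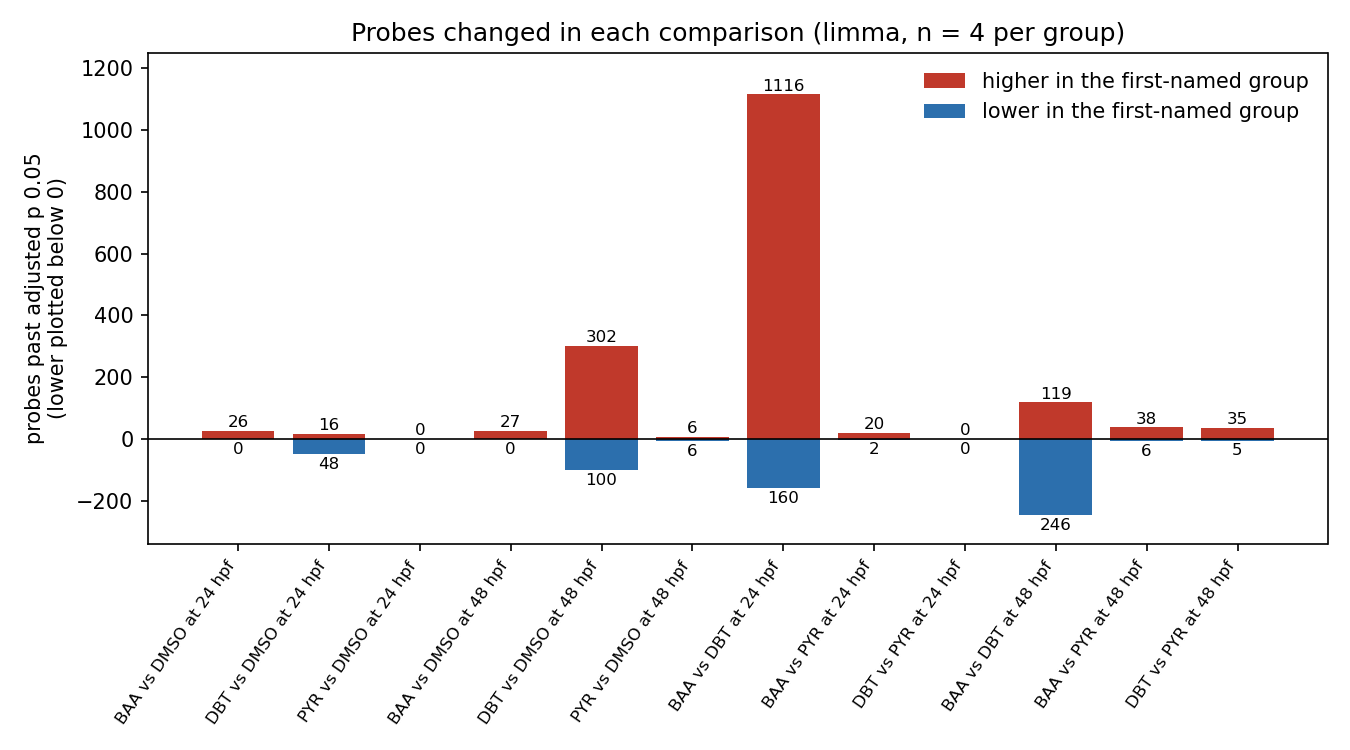
Number of probes past the adjusted p threshold (y axis, limma, 4 arrays per group) in each of 12 comparisons (x axis), with probes higher in the first-named group above 0 and lower probes below 0. DBT gave 302 higher and 100 lower probes against DMSO at 48 hpf, and PYR at 24 hpf gave none.

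Exposure to BAA raised genes of the aryl hydrocarbon receptor (AHR) response at 24 hpf. The largest rise was in cyp1a, a cytochrome P450 that oxidizes aromatic hydrocarbons and is the standard marker of AHR activation, which stood at 4.31 ± 0.20 in BAA embryos and 0.34 ± 0.47 in DMSO embryos (log2 ratio, SD, n = 4). This was a difference of at least 15.6-fold (log2 3.96, limma adjusted p = 2.84e-11), as saturation of the spot on 3 of the 4 BAA arrays caps the measured value. Its relatives rose too: cyp1b1 4.41-fold (log2 2.14, SE 0.22), cyp1c1 3.54-fold (log2 1.82, SE 0.29) and cyp1c2 2.14-fold (log2 SE 0.18). Dimmer probes of cyp1b1 (log2 0.35, 0.71) and cyp1c1 (0.88, 0.39) did not pass. The sulfotransferase sult6b1 rose by 1.07 (log2, SE 0.17, adjusted p = 0.00297). The cyp1a probe lies on chromosome 18 at 3973014 to 3973073 and the cyp1b1 probe on chromosome 13 at 42451180 to 42451239 of the Zv8 (danRer6) build. No annotation of that build was at hand to place them in an exon or UTR. The AHR repressor gene ahrra (log2 0.71, SE 0.27, adjusted p = 0.537) and tiparp, a polymerase gene that AHR induces (0.60, SE 0.18, adjusted p = 0.265), did not pass the test, and ahrrb was not above background.

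In all, 26 probes were higher and 0 lower in BAA than in DMSO embryos at 24 hpf (limma, 35023 probes tested, 2020 with an unadjusted p under 0.05), and the 26 stood for 16 named genes. Beside the genes above, the calls included the lens crystallins crygm3 (log2 1.58, adjusted p = 0.0329) and cryaa (1.20, adjusted p = 0.0306), and the stanniocalcin gene stc1l (1.39, adjusted p = 0.00177). They also included the collagen gene col10a1a (1.41, adjusted p = 0.0499). The forkhead gene foxq2 was counted too (adjusted p = 0.0447), but its spots were not well above background on any of the 8 arrays, so neither a fold nor a difference is given. With Feature Extraction's processed signals, the sample channel alone or the authors' table, these 5 genes lost their calls. In that order crygm3 fell to 0.33, 0.15 and 0.32, cryaa to 0.17, 0.11 and 0.16, stc1l to 0.57, 0.33 and 0.56, and col10a1a turned slightly negative, at -0.063, -0.044 and -0.071. A fixed slide block ended all of these calls but that of stc1l, and a random slide block and a scan day block those of foxq2 and col10a1a. Leaving out BAA replicate 1, 2 or 4 or DMSO replicate 1 or 3 ended the calls of crygm3, cryaa, foxq2 and col10a1a, as did DMSO replicate 4 for all but cryaa and DMSO replicate 2 for foxq2 and col10a1a. Adjusted p over all alternatives of these genes reached 1.0. Every log2 fold change between BAA and DMSO arrays of the same slide was positive for cyp1a (3.85 to 4.01, capped on the saturated arrays), cyp1b1 (1.81 to 2.30), cyp1c1 (1.53 to 2.12) and sult6b1 (0.72 to 1.20). The count was 9 with slide as a fixed block, 68 with a replicate block, and 4 and 41 within the respective scan days, and it ran from 8 with the other groups out of the fit to 899 with array weights. Single arrays moved it as well: it was 9 without BAA replicate 1, 17 without replicate 2, 541 without replicate 3 and 9 without replicate 4, and 11, 17, 9 and 11 without DMSO replicates 1, 2, 3 and 4.

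Among the gene lists, the AHR-responsive genes had 4 of 14 measured members higher with BAA at 24 hpf (7 adjusted over the list alone), with a mean log2 fold change of 0.83 (camera adjusted p = 1.49e-14, and adjusted p = 2.22e-05 with an estimated correlation). Their mean was 0.76, 0.73 and 0.92 within the 3 slides that held both groups. The lens and retina genes, which hold the crystallins, were shifted up by a mean of 0.31, with 2 of 38 members called (6 adjusted over the list alone); the camera adjusted p = 1.29e-05, but adjusted p = 0.689 with an estimated correlation. The immediate early and inflammation genes had a mean of 0.21 with 0 of 33 members called by limma (2 adjusted over the list alone; adjusted p = 0.015, and adjusted p = 0.689 with an estimated correlation). Within the respective scan days the means were 0.36 and 0.27 for lens and retina genes and 0.24 and 0.19 for inflammation genes. The other 21 lists were not called in this comparison.

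With DBT at 24 hpf the largest rise was in slc16a9b, a member of the monocarboxylate transporter family, at 1.42 ± 1.26 with DBT and -1.50 ± 0.19 with DMSO (log2 ratio, SD, n = 4), a 7.59-fold difference (log2 2.92, SE 0.47, limma adjusted p = 0.00779). Its probe lies on chromosome 12 at 7988426 to 7988485. plekhf1, an endosomal lipid-binding protein gene, rose 3.53-fold (log2 1.82, SE 0.34). Smaller rises were found in abat, which breaks down the neurotransmitter GABA (1.07), the sulfate transporter slc13a4 (0.96), the macrophage marker mfap4.1 (1.09) and the endothelial VEGF receptor kdr (0.66). Among the falls were soat2, which esterifies cholesterol (log2 -1.38, SE 0.26), elovl6, which elongates fatty acids (-0.70, SE 0.13), and hmgcs1, an early enzyme of cholesterol synthesis (-0.60, SE 0.13). The troponin gene tnni1d of the muscle filament fell by 1.32 (SE 0.22, adjusted p = 0.00779), and the muscle phosphofructokinase gene pfkma by 1.04. The selenium carrier gene selenop fell by 1.17, the clotting factor gene f7l by 1.23, the keratin gene krt91 by 1.08 and the Wnt antagonist gene sfrp1b by 1.05.

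The comparison called 64 probes for 48 named genes, 16 higher and 48 lower. None of the AHR panel passed: cyp1a differed by 0.23 (95% confidence interval -0.32 to 0.78), cyp1b1 by -0.29, cyp1c1 by 0.00 and cyp1c2 by -0.28. The count was 111 with the sample channel alone, 101 with a random slide block, 228 with array weights and 29 with the other groups out of the fit. DBT and DMSO arrays of this age shared no slide, so no within-slide value exists, and the count was 5 and 0 within the respective scan days. It fell to 2 without DBT replicate 1, 7 without replicate 3 and 19 without replicate 4, was 104 without replicate 2, and was 39, 14 and 14 without DMSO replicates 1, 2 and 4. Of the 24 genes named in this comparison by the rule, only tnni1d passed the test with each array left out in turn, and its call ended by the sample channel alone (adjusted p = 0.0727). The calls of slc16a9b and krt91 ended without DBT replicate 1 alone (adjusted p = 0.0548 and 0.0659), and that of sfrp1b without DBT replicate 1 or 3 or DMSO replicate 4 or by the sample channel alone (up to 0.0801). For soat2 and abat they ended without DBT replicate 1 or 3 or DMSO replicate 2 or 4 (up to 0.105 and 0.172), and for elovl6 and slc13a4 without DBT replicate 1, 3 or 4 or DMSO replicate 2 (up to 0.0675 and 0.103). plekhf1, selenop and f7l lost theirs without DBT replicate 1, 3 or 4 or DMSO replicate 2 or 4 (up to 0.108, 0.108 and 0.135), and so did pfkma, which also needed DMSO replicate 1 (up to 0.222). The calls of kdr, mfap4.1 and hmgcs1 ended in the authors' table, with the outlier spots kept, and without DBT replicate 1, 3 or 4 or DMSO replicate 2 (adjusted p up to 0.746, 0.911 and 0.248). That of hmgcs1 also ended with a replicate block, with a scan day block (adjusted p = 0.0610), without a filter and without any other DMSO replicate.

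With DBT at 24 hpf, 9 lists were shifted at the preset correlation, and none held with an estimated one. Of these, 5 were lower. The cholesterol biosynthesis genes had a mean of -0.23 with 1 of 24 members called (hmgcs1; 2 adjusted over the list alone; adjusted p = 0.00159, and adjusted p = 0.399 with an estimated correlation). The lens and retina genes had a mean of -0.25 with 0 of 38 called by limma (1 adjusted over the list alone; adjusted p = 0.000454, and adjusted p = 0.447 with an estimated correlation). Neural genes had a mean of -0.17, with the neurofilament gene nefmb called among 39 (1 adjusted over the list alone; adjusted p = 0.00189, and adjusted p = 0.473 with an estimated correlation). Pigment cell genes had a mean of -0.20, with melanosome transport gene mlpha called among 27 (7 lower and 1 higher adjusted over the list alone; adjusted p = 0.00239, and adjusted p = 0.399 with an estimated correlation). Skeletal muscle genes had a mean of -0.19 with 0 of 41 called (6 lower and 1 higher adjusted over the list alone; adjusted p = 0.00611, and adjusted p = 0.571 with an estimated correlation). The other 4 were higher. The immediate early and inflammation genes had a mean of 0.19 (0 of 33 called, 1 adjusted over the list alone; adjusted p = 0.00239, and adjusted p = 0.478 with an estimated correlation). Myeloid leukocyte markers had a mean of 0.16 (mfap4.1 called among 19, 4 adjusted over the list alone; adjusted p = 0.00173, and adjusted p = 0.399 with an estimated correlation). Vascular endothelial genes had a mean of 0.11 (kdr called among 27, 2 adjusted over the list alone; adjusted p = 0.00173, and adjusted p = 0.399 with an estimated correlation), and erythroid genes one of 0.07 (0 of 25 called, 0 adjusted over the list alone; adjusted p = 0.0467, and adjusted p = 0.571 with an estimated correlation). Erythroid genes turned direction between the respective scan days, at -0.14 and 0.27, and the mean lay mostly in 1 day for skeletal muscle (-0.044 and -0.34), vascular (0.036 and 0.18) and inflammation genes (0.31 and 0.065). It was -0.32 and -0.15 for cholesterol, -0.19 and -0.32 for lens and retina, -0.12 and -0.22 for neural, -0.11 and -0.29 for pigment and 0.17 and 0.15 for myeloid genes. Leaving out DBT replicate 1 ended the neural (adjusted p = 0.0713), pigment (0.0713) and muscle (0.136) calls, leaving out DBT replicate 3 the inflammation call (0.0883), and leaving out DMSO replicate 2 the muscle call (0.147). The erythroid call ended without DBT replicate 2 (0.455), DBT replicate 4 (0.198) or DMSO replicate 1 (0.872).

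PYR changed no probe against DMSO at 24 hpf. By limma 0 probes passed, 725 had an unadjusted p under 0.05 and the smallest adjusted p was 0.309. The processed signals, the sample channel alone, the authors' table, array weights and every block also gave 0, and 1 probe passed without PYR replicate 4. cyp1a differed from DMSO by 0.50 (95% confidence interval -0.05 to 1.05), cyp1c2 by 0.27, cyp1c1 by 0.18 and cyp1b1 by -0.33, none past the test. The list tests, which pool small shifts over many genes, called 6 lists at the preset correlation, and the adjusted p of each was 0.309 with an estimated correlation. They were lower for skeletal muscle genes (mean -0.16, adjusted p = 1.8e-05), cholesterol biosynthesis genes (-0.15, adjusted p = 0.000122) and neural genes (-0.12, adjusted p = 0.000122). They were higher for immediate early and inflammation genes (0.21, adjusted p = 1.8e-05), myeloid leukocyte markers (0.12, adjusted p = 0.000729) and p53 and DNA damage genes (0.06, adjusted p = 0.0448). Between the respective scan days the direction turned for skeletal muscle genes (0.053 and -0.37) and myeloid markers (-0.0040 and 0.24), and inflammation genes shifted mostly on 1 day (0.044 and 0.38). The means were -0.22 and -0.084 for cholesterol, -0.061 and -0.18 for neural and 0.083 and 0.045 for p53 genes. Adjusted over the list alone, 1 inflammation gene and 0 members of the other 5 lists passed. Single arrays ended the myeloid call (DMSO replicate 1, adjusted p = 0.0751; DMSO replicate 3, 0.0636) and the neural call (DMSO replicate 2, 0.0549; PYR replicate 3, 0.175). They also ended the muscle call (PYR replicate 2, 0.681) and the p53 call (DMSO replicate 2, 0.123; DMSO replicate 4, 0.162; PYR replicate 1, 0.0825; PYR replicate 3, 0.563).

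At 48 hpf BAA again raised AHR genes, and more members of the panel passed the test. cyp1a stood at 4.57 ± 0.07 with BAA against -0.28 ± 0.40 with DMSO (log2 ratio, SD, n = 4), at least 28.8-fold higher (log2 4.85, limma adjusted p = 8.67e-14), as spots were saturated on 2 BAA arrays. cyp1c1 was 17.1-fold higher (log2 4.09, SE 0.29), cyp1b1 5.73-fold (2.52, SE 0.22) and cyp1c2 4.23-fold (2.08, SE 0.18). The AHR feedback genes now passed: ahrra rose 5.89-fold (2.56, SE 0.27, adjusted p = 2.8e-07) and tiparp 2.19-fold (1.13, SE 0.18, adjusted p = 0.00124). ahrrb was above background on 3 BAA arrays and no DMSO array and did not pass. Outside the panel, wfikkn1, a secreted growth factor inhibitor, rose 4.19-fold (2.07, SE 0.28), ctsl.1, a cathepsin L protease gene with its probe on chromosome 17 at 30112192 to 30112251, rose 3.62-fold (1.86, SE 0.24), and sult6b1 rose 2.75-fold (1.46, SE 0.17). The antioxidant genes prdx1, a peroxiredoxin (at least 2.13-fold, adjusted p = 7.1e-05, as it was saturated on 1 BAA array), and pir, a pirin (2.20-fold, adjusted p = 0.00923), rose as well.

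There were 27 higher and 0 lower probes, for 16 named genes (708 with an unadjusted p under 0.05; 7 and 27 passed within the respective scan days and 24 with slide as a fixed block). Within slides cyp1a differed by 4.31 to 5.13 (capped on the saturated arrays), cyp1c1 by 3.91 to 4.39 and ahrra by 2.34 to 3.18. The count was 59 with the sample channel alone, and with the authors' table it was 36, of which 4 were lower. The call of pir ended without BAA replicate 1, BAA replicate 2 or DMSO replicate 4, with adjusted p up to 0.131. Across ages, 8 probes were higher with BAA at both, among them those of cyp1a, cyp1b1, cyp1c1, cyp1c2 and sult6b1, where independent overlap would give 0.02.

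**Figure D2:**
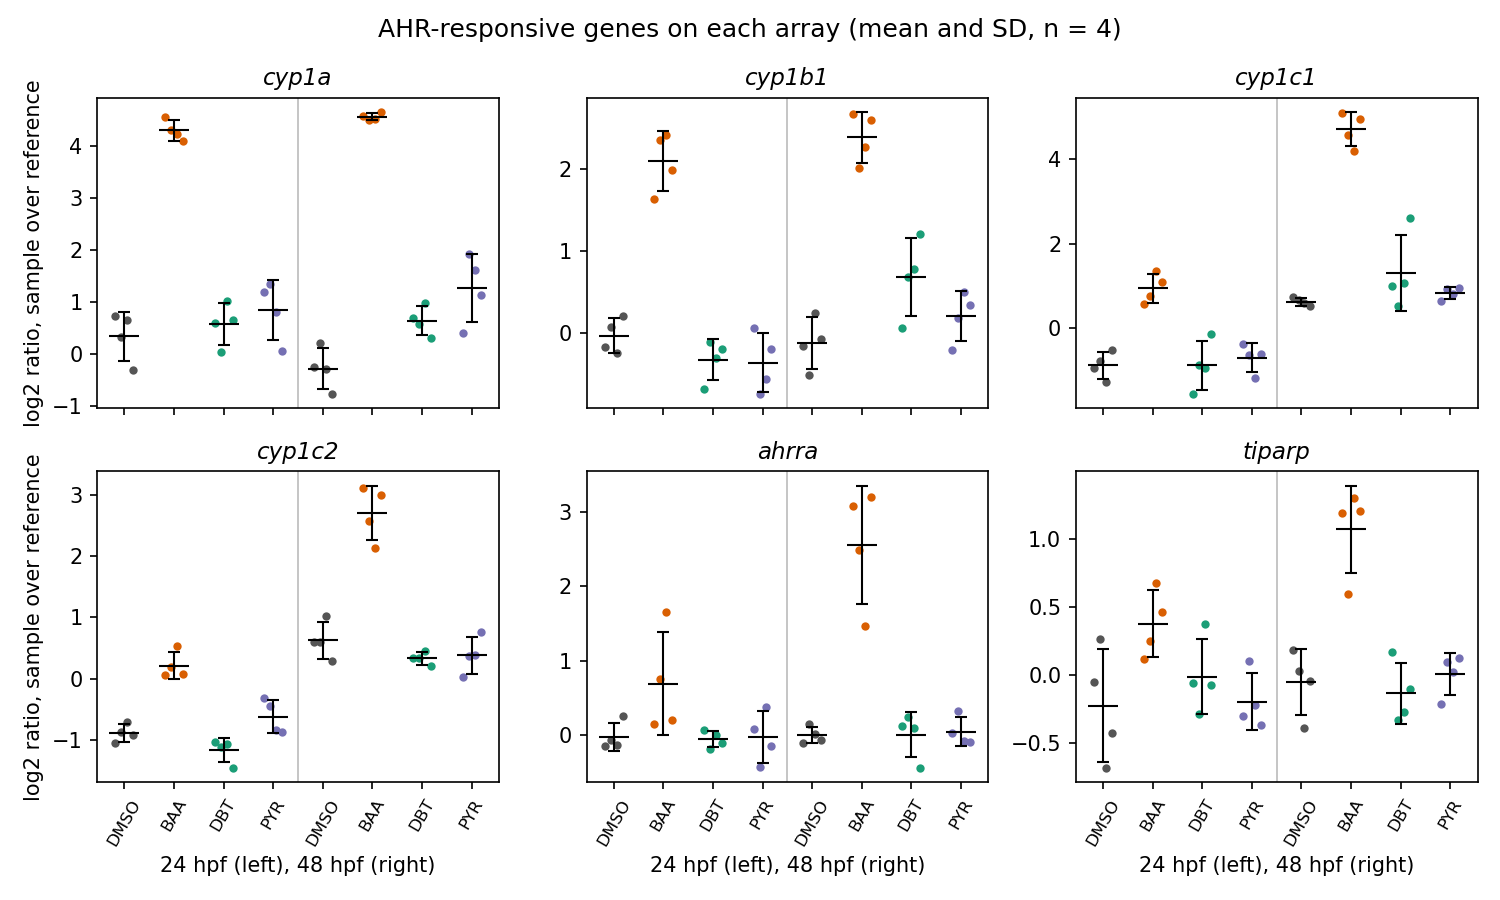
Log2 ratio of sample over pooled reference (y axis) for 6 AHR-responsive genes on each array, by compound (x axis), with 24 hpf left and 48 hpf right of the vertical line. Points are arrays, bars the mean and SD of 4 arrays; the 4 BAA arrays lie above all 4 DMSO arrays for cyp1a at both ages.

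Of the lists, the AHR-responsive genes had 6 of 14 members higher with BAA at 48 hpf (8 adjusted over the list alone, adding foxq1b and the receptor gene ahr2). Their mean was 1.34 (adjusted p = 9.46e-49, and adjusted p = 2.66e-10 with an estimated correlation), and 1.503, 1.199 and 1.329 within the 3 slides that held both groups. NRF2 and glutathione antioxidant genes, the targets of the oxidative stress regulator NRF2, had a mean of 0.28 (adjusted p = 4.89e-10, and adjusted p = 0.00122 with an estimated correlation; 0.15, 0.41 and 0.28 within slides). Of their 25 members prdx1 was called over all probes and 6 adjusted over the list alone, which added glutathione reductase gsr (1.01), gstp1.1 (1.18), sqstm1 (0.63), keap1a (0.55) and pgd (0.44), named after their values were seen. Cell cycle and replication genes were shifted down by a mean of -0.16, with 25 of 26 members negative and 0 called by limma or adjusted over the list alone (camera adjusted p = 4.89e-10, and adjusted p = 0.00925 with an estimated correlation; -0.04, -0.19 and -0.21 within slides). Another 3 lists were lower at the preset correlation, with 0 members called by limma over all probes or adjusted over the list alone. They were the cholesterol biosynthesis genes (mean -0.12, adjusted p = 0.00139, and adjusted p = 0.339 with an estimated correlation) and the fatty acid and lipid handling genes (-0.09, adjusted p = 0.0086, and adjusted p = 0.22 with an estimated correlation). The myeloid leukocyte markers were the last (-0.13, adjusted p = 0.00175, and adjusted p = 0.339 with an estimated correlation). Within the respective scan days the means of these 3 were -0.16 and -0.084, -0.024 and -0.16, and -0.094 and -0.18. Without BAA replicate 2, DMSO replicate 1 or DMSO replicate 3 the fatty acid call ended (0.0614, 0.114 and 0.0627), and without DMSO replicate 1 so did the myeloid call (0.0660).

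With DBT at 48 hpf the largest rise was in the sarcomere gene tcap, which caps titin, at 5.17-fold (log2 2.37, SE 0.47, limma adjusted p = 0.00683; probe on chromosome 3 at 19372887 to 19372946). The ventral homeobox gene vox rose 3.76-fold, from -2.03 ± 0.15 to -0.12 ± 0.43 (SD, n = 4; log2 1.91, SE 0.20). The chemokine receptor gene cxcr4a rose 3.04-fold, from -1.03 ± 0.10 to 0.58 ± 0.34 (SD, n = 4; log2 1.61, SE 0.15; probe on chromosome 9 at 7177854 to 7177913). Other rises were in the calcium hormone gene pth1a (2.82-fold), the neural adhesion gene prtga (2.77-fold), the proton pump gene tcirg1b (2.75-fold) and the small heat shock gene hspb9l (2.70-fold). Rises were also found in g6pc1a.1, which releases glucose (2.44-fold), the growth factor binding gene igfbp1a (2.12-fold), the transketolase gene tktb (log2 at least 0.81, as it was saturated on 1 DBT array) and sesn3 (0.90). The phototransduction gene gnb3a fell most, from 0.86 ± 0.28 to -1.10 ± 0.88 (SD, n = 4; log2 -1.96, SE 0.33, adjusted p = 0.00119). With it fell the G protein gene gng13b (-1.54), the retinal homeobox genes vsx1 (-1.37) and crx (-1.24), the photoreceptor calcium sensor gene rcvrna (-1.30), the troponin gene tnni4b.3 (-1.17) and ankrd1b of stretched muscle (-1.12).

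**Figure D3:**
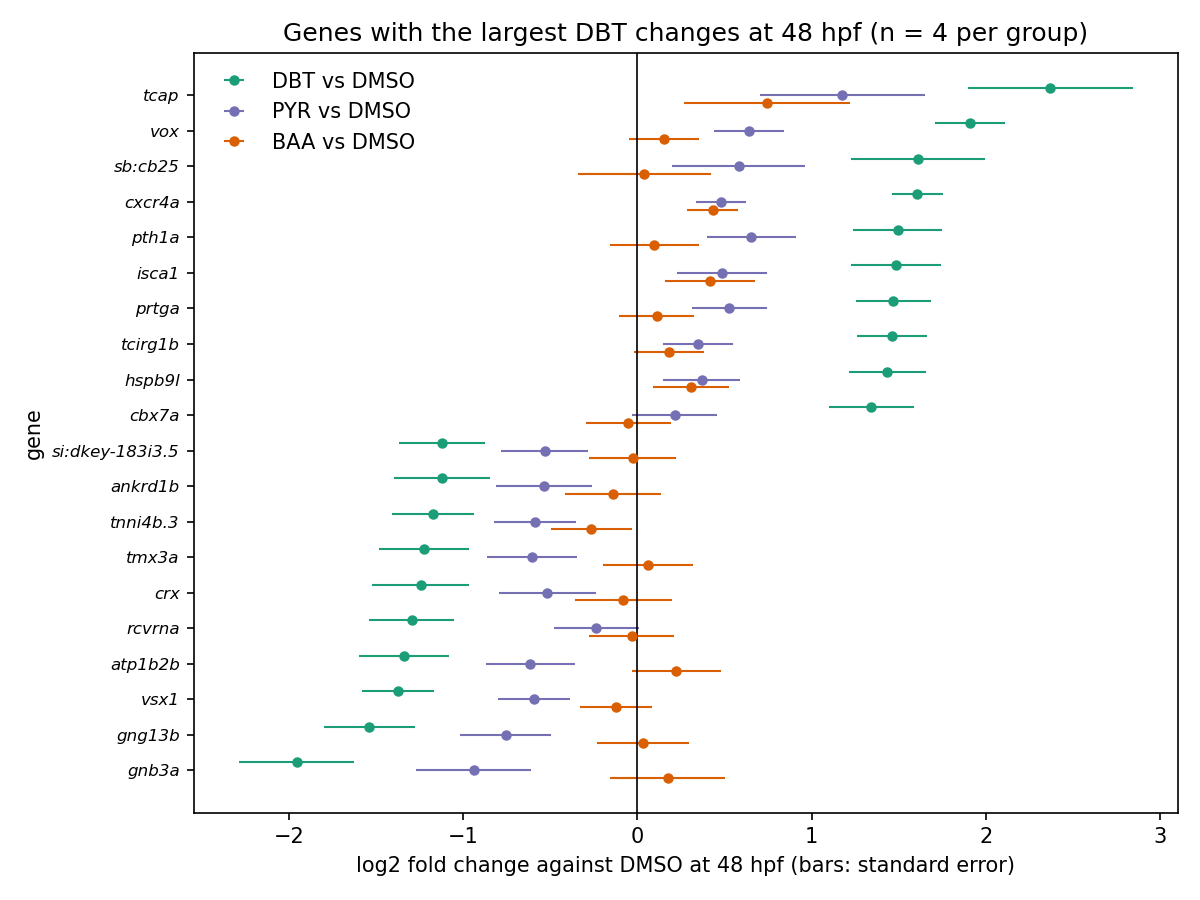
Log2 fold change against DMSO at 48 hpf (x axis) of the 10 genes with the largest DBT rises and the 10 with the largest falls (y axis), for DBT, PYR and BAA; points are fitted values and bars standard errors, 4 arrays per group. The genes were picked on the DBT values, which run from 2.37 for tcap to -1.96 for gnb3a.

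The comparison called 402 probes for 272 named genes, 302 higher and 100 lower, with 4875 at an unadjusted p under 0.05. DBT replicate 4, the bright array, was left out of every fit as a choice made after seeing the data: 273 probes then passed, 170 higher and 103 lower, of which 206 were among the 402. The share of higher probes changed with the scaling, with 317 of 610 higher by processed signals, 352 of 1383 by the sample channel alone and 377 of 658 by the authors' table. Array weights gave 1042 probes and a fit of only DBT and DMSO arrays 10. The count was 250, 1429 and 171 without DBT replicates 1, 2 and 3, and 222, 230, 173 and 219 without DMSO replicates 1, 2, 3 and 4. No slide held both groups, and 37 and 13 probes passed within the respective scan days. Of the 46 genes named by the rule, all kept their direction, and 26 their call under every planned setting apart from leaving out arrays. Without the bright array 32 kept their call, and with each array left out 22. Those kept with each array left out included vox, cxcr4a, pth1a, prtga, tcirg1b, hspb9l, tcap, gnb3a, gng13b and vsx1. By the sample channel alone the calls of g6pc1a.1, tnni4b.3 and rcvrna ended (adjusted p = 0.0505, 0.699 and 0.16), and that of crx ended in the authors' table, with the outlier spots kept and without DBT replicate 3 or DMSO replicate 1 or 4 (up to 0.0993). ankrd1b lost its call without DBT replicate 1 or 3 or any DMSO replicate (up to 0.106). In the AHR panel, cyp1a differed by 0.92 (95% confidence interval 0.37 to 1.47, adjusted p = 0.0901) and cyp1b1 by 0.81 (0.37 to 1.25, adjusted p = 0.0582), neither past the test. cyp1b1 did pass with a scan day block (adjusted p = 0.0401) and a random slide block (adjusted p = 0.0487). cyp1c1 (0.68), ahrra (0.01) and cyp1c2 (-0.29) did not pass.

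Among lists, the immediate early and inflammation genes had 7 of 33 members higher and 2 lower with DBT at 48 hpf (15 and 2 adjusted over the list alone). The higher members included the transcription factor fosl2 (1.17), the cytokine suppressors socs3b (1.05) and socs3a (1.04) and the stress factor atf3 (1.02), and the lower ones were the collagenase gene mmp13a (-0.87) and the flow-responsive klf2a (-0.45). The list's mean was 0.36 (adjusted p = 7.88e-05, and adjusted p = 0.605 with an estimated correlation). The lens and retina genes had 4 of 38 members lower, crygs1 (-0.74), cryaa (-1.08), vsx1 and crx, and rx1 higher (8 lower and 3 higher adjusted over the list alone), and a mean of -0.26 (adjusted p = 2.24e-06, and adjusted p = 0.605 with an estimated correlation). Cardiac genes had 3 of 22 members higher, the transcription factor gata5 (0.57), the myosin light chain cmlc1 (0.51) and rgs4 (0.80) (5 adjusted over the list alone; mean 0.20, adjusted p = 0.049, and adjusted p = 0.605 with an estimated correlation). Within the respective scan days the means were 0.56 and 0.17 for inflammation, -0.25 and -0.28 for lens and retina and 0.29 and 0.12 for cardiac genes. The calls of atf3, mmp13a, klf2a, rgs4 and cmlc1 ended without the bright array. That of rgs4 also ended with a replicate block and a scan day block (adjusted p = 0.0501), and that of mmp13a with a scan day block (adjusted p = 0.0546). Those of rgs4, cmlc1 and klf2a ended without any array but DBT replicate 2, that of mmp13a without any but DBT replicate 1, and that of atf3 without DMSO replicate 4 and by the sample channel alone. That of gata5 ended by processed signals, the sample channel alone and the authors' table and without DBT replicate 1 or 3 or DMSO replicate 1 or 4 (up to 0.144). crygs1 lost its call without DMSO replicate 1 or 2 (up to 0.058) and cryaa without DMSO replicate 4 (0.0803). The cardiac call ended without DBT replicates 1, 2 and 3 (adjusted p = 0.249, 0.133 and 0.212) and DMSO replicates 1, 3 and 4 (0.0584, 0.195 and 0.0906). Lists not called as a whole still held changed members. Vascular endothelial genes had 3 higher and 1 lower of 27 (cldn5b, clec14a and egfl7, and klf2a), and glycolysis and hypoxia genes 2 higher of 29 (g6pc1a.1, igfbp1a). Retinoid pathway genes had 2 higher of 23 (cyp26c1, which degrades retinoic acid, and rdh10b, which makes its precursor). Skeletal muscle genes had 1 higher (myf5) and 1 lower (myhb) of 41. Without the bright array the calls of cldn5b, g6pc1a.1, igfbp1a and myhb were kept, and those of egfl7, clec14a, cyp26c1, rdh10b and myf5 ended. That of cldn5b ended without DBT replicate 1 or 3 or DMSO replicate 3 or 4 (up to 0.0951), and that of myhb without DBT replicate 3 and by the sample channel alone (up to 0.402).

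PYR at 48 hpf changed few genes, and cyp1a and the sterol pathway were among them. cyp1a was 2.93-fold higher, at 1.27 ± 0.66 against -0.28 ± 0.40 (log2 ratio, SD, n = 4; log2 1.55, SE 0.27, limma adjusted p = 0.00873). The finTRIM gene ftr86, of a fish family of tripartite motif genes, rose 2.24-fold (1.17, SE 0.18, adjusted p = 0.00291), and the calcium-binding s100z (1.05) and the oxidase gene duox1 (1.04) rose as well. cyp51, the lanosterol demethylase of cholesterol synthesis, fell from 0.11 ± 0.28 to -1.03 ± 0.14 (SD, n = 4; log2 -1.14, SE 0.17, adjusted p = 0.00291; probe on chromosome 19 at 505417 to 505476). The purine nucleoside phosphorylase gene pnp4b (-2.29, SE 0.39) and the aminotransferase gene agxtb (-2.38, SE 0.44), which detoxifies glyoxylate, fell most. The comparison called 12 probes for 7 named genes, 6 higher and 6 lower (1284 with an unadjusted p under 0.05). ftr86 and cyp51 passed under every setting and with every array left out. The call of cyp1a ended with processed signals and without DMSO replicate 3 or 4 or PYR replicate 2 or 3 (adjusted p up to 0.112), and that of pnp4b without DMSO replicate 3 or PYR replicate 3 or 4 (up to 0.0674). agxtb lost its call without DMSO replicate 1, 2 or 3 or PYR replicate 1, 3 or 4 (up to 0.138). So did s100z without any of the 8 arrays (up to 0.281) and duox1 without any but PYR replicate 3 (up to 0.31). The strict filter, keeping the outlier spots and a scan day block (adjusted p = 0.0508 for each) also ended these last calls. The count was 3 without DMSO replicate 3, 5 without PYR replicate 3, 7 without PYR replicate 4, 6 under the strict filter, 20 by processed signals, 65 by the sample channel alone and 27 with array weights. PYR and DMSO arrays of this age shared no slide, and 0 and 8 probes passed within the respective scan days.

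The cholesterol biosynthesis genes were lower as a group with PYR at 48 hpf, with a mean of -0.37 over 24 members (adjusted p = 3.75e-17, and adjusted p = 0.00838 with an estimated correlation) and of -0.42 and -0.33 within the respective scan days. Over all probes cyp51 alone was called, and adjusted over the list alone 11 members were lower. The lower members included hsd17b7 (-0.89), the lanosterol synthase lss (-0.88), msmo1 (-0.76), sc5d (-0.76) and the rate-limiting HMG-CoA reductase gene hmgcra (-0.73), all named after their values were seen. At the preset correlation the fatty acid and lipid handling genes were lower (mean -0.14, 0 of 26 called, 1 adjusted over the list alone; adjusted p = 0.00726, and adjusted p = 0.267 with an estimated correlation). So were the lens and retina genes (-0.13, 0 of 38 called, 0 adjusted over the list alone; adjusted p = 0.00726, and adjusted p = 0.913 with an estimated correlation). Erythroid genes were higher (0.12, 0 of 25 called, 0 adjusted over the list alone; adjusted p = 0.0349, and adjusted p = 0.913 with an estimated correlation). Within the respective scan days the means of these 3 lists were -0.067 and -0.21, -0.13 and -0.13, and 0.11 and 0.13. Without DMSO replicate 1 the erythroid, fatty acid and lens calls ended (adjusted p = 0.207, 0.148 and 0.154), without PYR replicate 2 the erythroid (0.152) and lens (0.173) calls, and without PYR replicate 4 the erythroid call (0.234).

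**Figure D4:**
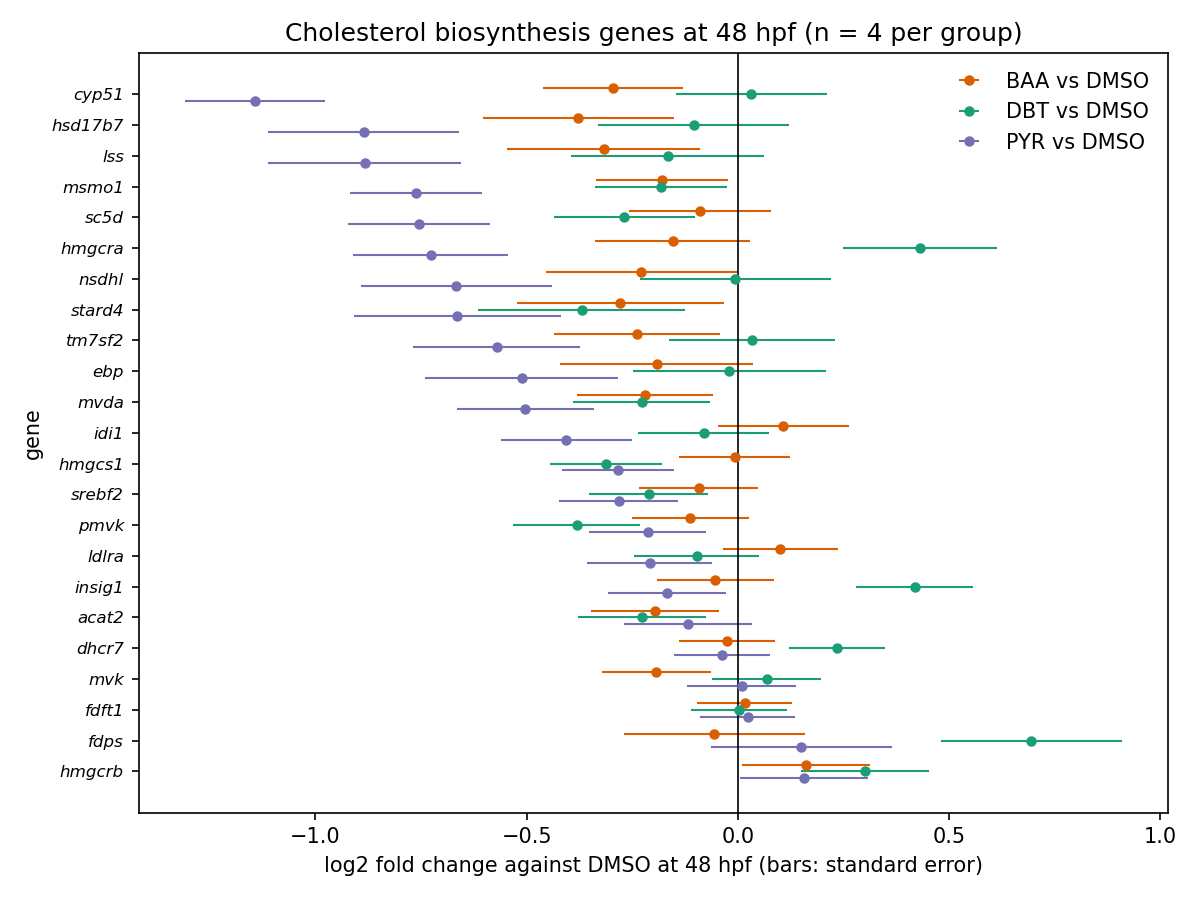
Log2 fold change against DMSO at 48 hpf (x axis) of 23 of the 24 measured cholesterol biosynthesis genes (y axis) for BAA, DBT and PYR; points are fitted values and bars standard errors, 4 arrays per group. With PYR cyp51 lies at -1.14 and hmgcra at -0.73.

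Over the 6 comparisons with DMSO, 144 list tests were made and 31 were called at the preset correlation, of which 5 held with an estimated correlation. These were the AHR-responsive genes with BAA at both ages, the NRF2 and glutathione antioxidant genes and the cell cycle and replication genes with BAA at 48 hpf, and the cholesterol biosynthesis genes with PYR at 48 hpf. Called in no comparison were 9 lists, with lowest adjusted p of 0.0619 for liver and yolk syncytial layer genes, 0.0842 for glycolysis and hypoxia genes, 0.0859 for other xenobiotic metabolism genes, and 0.0896 for epidermis and ionocyte genes. It was 0.101 for hatching gland genes, 0.223 for heat shock and unfolded protein response genes and for retinoid pathway genes, and 0.371 for cartilage, bone and matrix genes and for circadian clock genes.

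**Figure D5:**
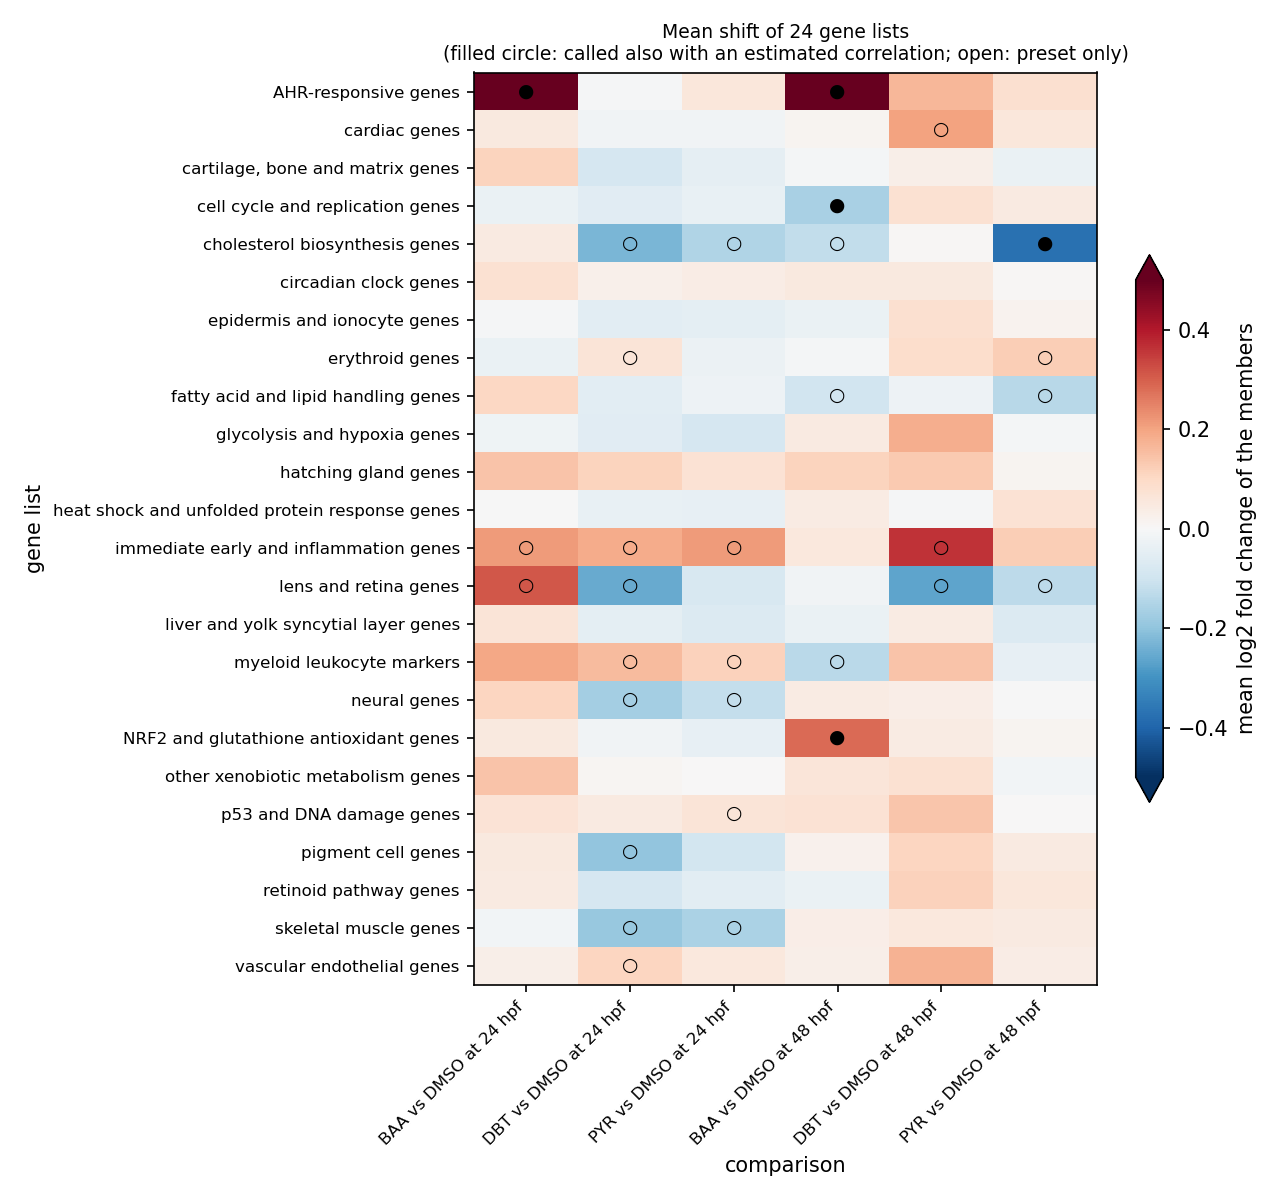
Mean log2 fold change of the measured members (colour, clipped at the ends of the scale) of 24 gene lists (y axis) in 6 comparisons with DMSO (x axis). A filled circle stands for a call at the preset and with an estimated correlation, an open circle for a call at the preset alone; filled circles stand at AHR-responsive genes for BAA at both ages and at cholesterol biosynthesis genes for PYR at 48 hpf.

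Set against each other at the same dose and age, BAA and the other compounds differed in the AHR panel. At 24 hpf cyp1a was higher with BAA than with DBT by at least 3.73 (adjusted p = 1.54e-10) and than with PYR by at least 3.46 (adjusted p = 1.18e-09) on the log2 scale, as saturation on 3 of the 4 BAA arrays caps these differences. For cyp1b1 they were 2.43 and 2.47. Against PYR the cyp1c1 difference was 1.65 (adjusted p = 0.0115). BAA also exceeded DBT in fabp4b, a fatty acid carrier gene (2.39, adjusted p = 0.000138), and in the lens genes grifin (2.04) and lctla (at least 2.44-fold, as the DBT arrays were not above background). slc16a9b (-2.46), plekhf1 (-1.50) and abcb11a, a bile salt transporter gene (-1.06), were lower. Against PYR, cryaa (1.33) and the troponin gene tnni2b.2 (1.295) were higher with BAA. The calls of grifin, lctla, abcb11a, cryaa and tnni2b.2 ended with processed signals, the sample channel alone and the authors' table. Without DBT replicate 3 plekhf1 did not pass (adjusted p = 0.0501), and against PYR cyp1c1 did not without BAA replicate 4 or PYR replicate 3 (up to 0.119). cryaa and tnni2b.2 were lost without BAA replicate 1 or 4 or PYR replicate 3, and tnni2b.2 also without PYR replicate 1 or 2 (adjusted p over all alternatives up to 1.0 and 0.81). BAA and DBT differed at 1276 probes for 751 named genes, 1116 higher and 160 lower with BAA, and BAA and PYR at 22, 20 higher and 2 lower.

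The BAA and DBT count at 24 hpf was 193 by processed signals, 175 by the authors' table, and 221 higher and 91 lower by the sample channel alone. It was 5548 with array weights (3817 higher) and 1944 with the other groups out of the fit (1289 higher). It was 5 and 558 within the respective scan days, 614, 2396 and 385 without BAA replicates 1, 3 and 4, and 655 without DBT replicate 1. For BAA against PYR it was 14 by processed signals and by the authors' table, 53 without the bright array, 812 with array weights, 43 with a replicate block and 6 with only those groups, and 3 and 79 within scan days. Without BAA replicates 1, 3 and 4 it was 9, 528 and 6, and without PYR replicates 1, 2, 3 and 4 it was 13, 12, 6 and 54. DBT and PYR did not differ at any probe at 24 hpf: limma called 0, with 1311 at an unadjusted p under 0.05, processed signals called 1, and the sample channel alone, the authors' table, array weights and slide blocks called 0. Their difference in cyp1a was -0.27 (95% confidence interval -0.82 to 0.28) and in cyp1c2 -0.55 (-0.92 to -0.18, adjusted p = 1.0), DBT minus PYR.

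At 48 hpf the panel separated BAA from both again. BAA exceeded DBT in cyp1a by at least 3.93 (adjusted p = 1.24e-11; spots saturated on 2 BAA arrays), cyp1c1 by 3.41, ahrra by 2.55 and cyp1c2 by 2.37. It exceeded PYR in cyp1c1 by 3.89 (adjusted p = 1.4e-10), cyp1a by at least 3.30, ahrra by 2.51, cyp1c2 by 2.32 and cyp1b1 by 2.19. The cone gene gnb3a was 2.13 higher and vox (-1.76), zgc:162608 (-1.65) and pth1a (-1.40) lower with BAA than with DBT; sb:cb25 (-1.57) and arf4b (-1.41) were lower too, but their calls ended without the bright array. Lower with BAA than PYR were ftr86 (-0.89), anxa1b (-0.87), the myosin chaperone gene unc45b (-0.77) and zgc:152977 (-0.58, but 0.026 by the sample channel alone). The calls of these 4 ended by processed signals and in the authors' table and without BAA replicate 2, and for all but zgc:152977 without PYR replicate 4 (adjusted p over all alternatives up to 0.123, 0.247, 0.281 and 1.0). That of zgc:162608 ended without BAA replicate 2 (0.0603). The desaturase gene fads2 was 3.15-fold higher with DBT than PYR (log2 1.65, SE 0.26, adjusted p = 0.0024, and 0.0145 with slide as a fixed block), cyp51 1.17 higher and hmgcra 1.16 higher. Within slides the differences were 1.13 to 1.96, 0.83 to 1.41 and 0.71 to 1.33. vox (1.27) and fosl2 (1.21) were also higher with DBT than PYR, and the lens gene crygmxl1 lower (-1.30, adjusted p = 0.0139; up to 0.0751 without DBT replicate 3 or PYR replicate 1 or 4). The heat shock gene hspa1b (-0.71), hfm1 (-0.64, but 0.49 by the sample channel alone) and camkk1b (-0.61, but 0.042 by the sample channel alone) were lower, and lost their calls with a slide block and without the bright array. In cyp1a DBT minus PYR was -0.63 (95% confidence interval -1.18 to -0.08, adjusted p = 0.459), in cyp1b1 0.48 (0.04 to 0.92, adjusted p = 0.483) and in cyp1c1 0.47 (-0.12 to 1.07, adjusted p = 0.594), none past the test.

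At 48 hpf BAA and DBT differed at 365 probes (119 higher and 246 lower with BAA), BAA and PYR at 44 (38 and 6) and DBT and PYR at 40 (35 and 5). The BAA and DBT split was 165 higher and 160 lower without the bright array, 279 and 292 by processed signals and 855 and 308 by the sample channel alone, and 24 probes passed with only those groups in the fit. That count was 211, 129 and 239 without BAA replicates 1, 2 and 4, and 1249 and 202 without DBT replicates 2 and 3. The BAA and PYR count was 28 without BAA replicate 2, 69 by processed signals and 144 by the sample channel alone. The DBT and PYR count was 25 and 261 without DBT replicates 1 and 2, and 20 and 25 without PYR replicates 1 and 3. It was 132 by the sample channel alone (56 higher) and 0 with only those groups, and 33 with slide as a fixed block. Within the respective scan days the counts were 24 and 77 for BAA against DBT, 5 and 37 for BAA against PYR, and 3 and 0 for DBT against PYR.

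The effect of a compound was also compared between ages. For BAA 2 probes passed, both for cyp1c1. They gave a rise of 0.88 at 24 hpf and 3.18 at 48 hpf for the first (difference 2.30, SE 0.28, limma adjusted p = 8.06e-05) and 0.39 and 2.89 for the second (SE of the difference 0.44, adjusted p = 0.0397). They were named after their values were seen, and a brighter cyp1c1 probe differed by 2.27 (95% confidence interval 1.43 to 3.11, adjusted p = 0.0518). Here lists were tested after the data were seen, for BAA only. AHR-responsive genes had a higher BAA effect at 48 than at 24 hpf (camera adjusted p = 6.17e-07, and 0.00357 with an estimated correlation). So had NRF2 and glutathione antioxidant genes (adjusted p = 3.24e-05 and 0.0352 likewise). For ahrra the difference was 1.84 (95% confidence interval 1.07 to 2.62) and for cyp1c2 0.98, neither past the test. None is given for cyp1a, a list member saturated on BAA arrays at both ages. For DBT 12 probes passed, 11 with a higher and 1 with a lower effect at 48 hpf. Of the named genes, tcap went from -1.29 to 2.37 (difference 3.66, adjusted p = 0.0261), hspb9l from -0.87 to 1.44 (2.30), pth1a from -0.52 to 1.49 (2.01), s100z from -0.31 to 1.24 (1.56) and the muscle methyltransferase gene mettl21e from -0.43 to 1.01 (1.43). In ggctb, a glutathione breakdown gene, the effect went from 0.48 to -0.49 (-0.97, adjusted p = 0.0371). cxcr4a (1.39), the transcription factor gene onecut1 (1.12), trib3 (0.91) and cbsb (0.86) made up the rest with 2 probes without a symbol, as seen afterwards. hspb9l and mettl21e passed with every array left out, and the highest adjusted p with 1 array left out was 0.0929 for tcap and pth1a, 0.12 for s100z and 0.103 for ggctb. PYR had 0 probes by limma, with 873 at an unadjusted p under 0.05. It had 3 by processed signals, 11 by the sample channel alone, 4 with only those groups, 2 with array weights, 2 without the bright array, and 1 by the authors' table and with a random slide block.

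Single arrays moved these interaction counts. For BAA it was 106 without BAA replicate 3 at 24 hpf, 7 without BAA replicate 3 at 48 hpf. It was 1 without BAA replicates 1, 2 or 4 at either age, DMSO replicates 1, 3 or 4 at 24 hpf or DMSO replicates 1, 2 or 3 at 48 hpf. The DBT count was 5 and 7 without DBT replicates 1 and 2 at 24 hpf, and 5, 78 and 29 without DBT replicates 1, 2 and 4 at 48 hpf. It was 4 and 7 without DMSO replicates 1 and 2 at 24 hpf, and 7 and 6 without DMSO replicates 2 and 4 at 48 hpf. The PYR count was 1 without DMSO replicate 3 at 24 hpf and 2 without DMSO replicate 4 at 48 hpf. Settings took the DBT count to 53 by processed signals, 335 by the sample channel alone (109 higher), 52 by the authors' table, 48 with a random slide block, 26 with a replicate block and 133 with array weights. Within the respective scan days it was 0 and 0, and for BAA 0 and 8.

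Between DMSO embryos of 24 and 48 hpf, 11673 probes for 6071 named genes differed, 6234 higher and 5439 lower at 48 hpf. The largest rises were in the muscle deaminase gene ampd1 (log2 8.48), the lens genes crygm2b (7.66) and lctla (6.84), the troponin gene tnni2b.2 (7.34) and zgc:136930 (at least 7.49, as it was saturated on 2 arrays at 48 hpf). prtga (-4.45 or below, as it was saturated on 2 arrays at 24 hpf), the troponin genes tnnt1 (-4.24) and tnnt2c (-4.24), the Nodal antagonist gene lft2 (-3.91) and the exchanger gene slc8a4b (-3.85) fell most. All 10 kept their calls under every setting and without each array, and 5365 and 8297 probes passed within the respective scan days. With a fold of at least 1.5 required, 7528 probes remained. The 24 and 48 hpf arrays correlated at -0.45 to -0.05 across probes (median -0.26, 240 pairs), against 0.624 to 0.914 among 24 hpf arrays and 0.376 to 0.749 among 48 hpf arrays without the bright one. Its correlation with them was 0.175 to 0.341.

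The responses to the compounds were compared across the 35023 probes, which are not independent replicates. At 24 hpf the correlation of log2 fold changes was -0.0232 between BAA and DBT, 0.327 between BAA and PYR and 0.585 between DBT and PYR. As the comparisons share the DMSO arrays, 200 simulated data sets without any effect already gave 0.492 on average, with 95% of them between -0.153 and 0.871, a range that holds all 3 values. With the DMSO arrays split between the compounds the 3 values were -0.297, -0.138 and 0.0036. At 48 hpf the correlations were 0.285, 0.353 and 0.505 (split -0.0264, -0.0823 and 0.155), again within the simulated range of -0.164 to 0.870 (mean 0.446), and DBT and PYR gave 0.630 without the bright array. The BAA and DBT value at 24 hpf turned positive by the sample channel alone (0.0809) and without a filter (0.0312), and ran from -0.0743 to 0.133 with 1 array left out. For the same compound across ages the correlation was 0.127 for BAA, 0.207 for DBT and 0.0333 for PYR. Of called probes, DBT and PYR at 48 hpf shared 4 higher, with duox1, ftr86 and s100z, and 4 lower, with agxtb and pnp4b. BAA and PYR shared 1, for cyp1a, and BAA and DBT shared 0 at 24 hpf and 0 at 48 hpf. These comparisons share the DMSO arrays, and the overlap was not tested. DBT at both ages shared 1 higher, for slc13a4 (0.138 under independence), and 3 lower, for cfd, pfkma and selenop (0.137).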

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

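Tests chosen after the result was seen were the permutation of the stage score, the fit without the bright array, the within-slide comparison of cholesterol genes and their list with 1 array left out. The within-slide comparison of DBT with PYR was added after the DBT counts and the ratio of PYR to DBT had been seen, with its bounds written before its own values were; the counts of other splits and the remaining tests were planned before.

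Genes with an effect that differed between ages came first. The BAA effect differed at 2 probes, both of the AHR target cyp1c1 (differences 2.30 and 2.502 on the log2 scale), and 19 was the most from any of the other 99 splits drawn, so chance could not be excluded (6 of 100 gave as many). The DBT effect differed at 12 probes, led by tcap (3.66), hspb9l (2.30), pth1a (2.01), s100z (1.56), mettl21e (1.43) and ggctb (-0.97), and with up to 45 in other splits chance could not be excluded (5 of 100). Of 228 sets of 4 arrays tested for named genes, 7 had 1 array apart, where chance gives 11.4. These were ahrrb in BAA replicate 3 at 24 hpf (0.25, others -0.02 to 0.02), tiparp in BAA replicate 2 at 48 hpf (0.60, others 1.19 to 1.302) and slc16a9b in DBT replicate 2 at 24 hpf (-0.44, others 1.88 to 2.31). The others were igfbp1a in DBT replicate 4 at 48 hpf (0.40, others 1.44 to 1.59), abat (-1.94, others -0.999 to -0.876) and elovl6 (-0.70, others -0.42 to -0.37) in DMSO replicate 4 at 24 hpf, and klf2a in DMSO replicate 2 at 48 hpf (1.06, others 0.77 to 0.80).

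Of 56 sets of array measures, 10 had 1 array apart, where chance gives 2.8. DBT replicate 4 at 48 hpf stood out in Cy5 spots above background (43773, others 25538 to 26662), outlier spots (2913, others 19 to 42), Cy3 median intensity (983, others 185 to 247) and Cy5 median intensity (1572, others 247 to 273). DBT replicate 1 at 24 hpf had 878 outlier spots (others 17 to 20), and BAA replicate 3 at 48 hpf had an SD of 0.233 from its group mean (others 0.201 to 0.203). Replicate 2 of BAA and of DMSO at 24 hpf and of DBT and of PYR at 48 hpf, all on slide 3, had 0 saturated Cy3 spots (others 609 to 657, 597 to 716, 561 to 661 and 587 to 701).

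Other splits of a comparison's 8 arrays were counted too. For 7 counts no other split gave as many (1 of 35, the lowest share possible, unadjusted over tests). They were DBT at 24 hpf (64, highest other 0), and BAA (27, highest other 3), DBT (402, highest other 23) and PYR (12, highest other 1) at 48 hpf against DMSO. The others were BAA against DBT at 24 hpf (1276, highest other 463), BAA against PYR at 48 hpf (44, highest other 1) and the DMSO ages (11673, highest other 3). Of these 7, only BAA against DMSO at 48 hpf compared groups that shared slides, so the rest do not separate group from slide. Chance could not be excluded for BAA at 24 hpf (26, highest other 407, 3 of 35) or BAA against PYR at 24 hpf (22, highest other 484, 3 of 35). Nor could it for DBT against PYR at 48 hpf (40, highest other 372, 3 of 35) or BAA against DBT at 48 hpf (365, highest other 1012, 2 of 35). For PYR at 24 hpf (highest other 3), DBT against PYR at 24 hpf (highest other 14) and the PYR effect between ages (highest other 1) the real count by limma was 0, with the unadjusted counts as in the report. Every split then gave as many by construction (35 of 35, 35 of 35 and 100 of 100), which says nothing about chance. Splits with several times the real count point to a structure of the samples: for BAA at 24 hpf the highest set BAA replicates 1, 2 and 4 with DMSO replicate 2 against the rest. At 48 hpf it set BAA replicates 1, 2 and 4 with DBT replicate 2 apart, and DBT replicates 1, 3 and 4 with PYR replicate 2. For BAA against PYR at 24 hpf, the split by scan day gave 284; within the scan days the real comparison gave 3 and 79.

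At 24 hpf BAA arrays lay nearer to the 48 hpf arrays than DMSO arrays did, with a stage score (position along the difference between ages in the other compounds) of 0.226 ± 0.144 against 0.0562 ± 0.0661 (SD, n = 4), and chance could not be excluded (exact two-sided permutation p = 0.0857, and 0.257 adjusted over 6 such tests). BAA was higher within each of slides 1, 3 and 5, by 0.245, 0.0557 and 0.189 (mean 0.163, SE 0.0562). The direction thus held within slides, but 3 slides are too few to exclude slide or scan differences. The called probes and the AHR list carried little of the difference (0.983 kept without them), as so few of 33620 probes would anyway. A candidate explanation, that BAA embryos were further along in development, stays open: probes rising with age had a median BAA change of 0.37 and falling ones -0.06, a gap of 0.427 which 3 of 35 splits reached (largest other 0.537). The bound set before that count was seen, a gap within the other splits, was met and would have excluded the explanation, but the bound was wrong: a value inside the other splits does not show that no difference exists. BAA replicate 3 (0.0491) lay within the DMSO range of -0.0158 to 0.135, and exchanging it with DMSO replicate 2 or 4 gave the 2 larger gaps, 0.537 and 0.443, so a shift carried by 3 of 4 arrays cannot be excluded by such a ranking.

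With all groups in the fit DBT changed more probes than BAA or PYR against DMSO at 48 hpf, vox, cxcr4a and gnb3a among them, but with only the groups compared the counts were 10 for DBT, 19 for BAA and 16 for PYR. Within scan days they were 37, 7 and 0 on the first and 13, 27 and 8 on the second. The bright array is argued against as the cause in the fit of all groups, since without it DBT still gave 273 probes against 34 for BAA and 15 for PYR, a ratio of 8.03 to the larger. Slide differences between DBT and DMSO arrays stay open: on probes picked without a slide's own arrays, DBT minus PYR within that slide, in the direction of the DBT change, was 0.592, -0.0549 and 0.591 on slides 1, 3 and 8 (mean 0.376, SE 0.216; mean 0.457, SE 0.219 without the bright array), where slides as the whole cause would give 0. PYR arrays, on the same slides, changed the DBT probes by a median of 0.377 of the DBT change, with the same sign at 390 of 402; that is under the bound of 0.5 set beforehand to exclude slides, but the bound was wrong, as picking probes on the DBT change lowers the ratio whatever the cause. Untested as causes were a stronger DBT response and slower development (stage score -0.095 against DMSO).

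Cholesterol biosynthesis genes were lower with PYR than with DMSO at 48 hpf. Slide differences are argued against, as PYR was below DBT on slides 1, 3 and 8 by -0.415, -0.163 and -0.471 (mean -0.350, SE 0.0946; -0.241, SE 0.0870 without the bright array). Probes near background are argued against by 22 of 24 members above background on all 8 arrays. An adjusted p of at most 4.64e-12 with any array left out, run only at the preset correlation, argues against 1 deciding array. cyp51 passed every planned setting, but the list was not run on processed signals or the authors' table. Lower sterol gene expression after PYR may be biological, a hypothesis found and tested on these arrays, with slide differences not excluded.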

How the results depend on the processing

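The fit without the bright array, scan day as a block and lists with 1 array left out were chosen after seeing the data; other settings were planned. With Aquantile scaling, which alters only the average intensity, all log2 ratios and counts were identical by construction. The genes kept under every planned setting, of those named, were 11 of 11 for BAA against DMSO at 48 hpf, 5 of 10 at 24 hpf, 18 of 24 and 26 of 46 for DBT at 24 and 48 hpf, 4 of 7 for PYR at 48 hpf, 6 of 6 for the DBT effect between ages and 10 of 10 between DMSO ages. Signal over background limits foxq2 and ahrrb, and saturation limits cyp1a, prdx1, tktb, zgc:136930 and prtga. The cause of the changes below was not tested, except that a fit with only the groups compared has fewer arrays and a higher fold threshold or stricter filter leaves fewer probes.

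Processed signals gave 14 probes for BAA at 24 hpf, 610 for DBT at 48 hpf and 20 for PYR at 48 hpf against DMSO. Between compounds they gave 193 (BAA, DBT), 14 (BAA, PYR) and 1 (DBT, PYR) at 24 hpf and 571 (BAA, DBT) and 69 (BAA, PYR) at 48 hpf, and interactions of 53 (DBT) and 3 (PYR). col10a1a was reversed, at -0.063.

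With the Cy3 channel alone the counts against DMSO were 16 for BAA and 111 for DBT at 24 hpf, and 59 for BAA, 1383 for DBT and 65 for PYR at 48 hpf. Between compounds they were 312 (BAA, DBT) at 24 hpf, and 1163 (BAA, DBT), 144 (BAA, PYR) and 132 (DBT, PYR) at 48 hpf, with interactions of 10 (BAA), 335 (DBT) and 11 (PYR). Reversed were col10a1a (-0.044), camkk1b (0.042), hfm1 (0.49), zgc:152977 (0.026) and the correlation of BAA and DBT at 24 hpf (0.0809).

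The authors' table gave 14 (BAA, 24 hpf), 658 (DBT, 48 hpf) and 19 (PYR, 48 hpf) against DMSO, 175 (BAA, DBT) and 14 (BAA, PYR) at 24 hpf and 620 (BAA, DBT) at 48 hpf. Its interactions were 1 (BAA), 52 (DBT) and 1 (PYR), col10a1a stood at -0.071, and the median of all probes between DMSO ages moved by -0.11.

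Array weights gave 899 (BAA) and 228 (DBT) at 24 hpf and 1042 (DBT) and 27 (PYR) at 48 hpf against DMSO, 5548 (BAA, DBT) and 812 (BAA, PYR) at 24 hpf, 724 (BAA, DBT) and 122 (DBT, PYR) at 48 hpf, and interactions of 37 (BAA), 133 (DBT) and 2 (PYR).

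Without the bright array the counts were 68 (BAA) and 1.1e2 (DBT, rounded) against DMSO and 53 (BAA, PYR) at 24 hpf, and interactions 4 (BAA), 29 (DBT) and 2 (PYR); the erythroid list was called in 1 comparison in place of 2. With only the groups compared in the fit the counts were 8 (BAA) and 29 (DBT) against DMSO at 24 hpf and 10 (DBT) at 48 hpf, 1944 (BAA, DBT) and 6 (BAA, PYR) at 24 hpf, 24 (BAA, DBT) and 0 (DBT, PYR) by limma at 48 hpf, and 4 for the PYR interaction.

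A replicate block gave 68 (BAA against DMSO, 24 hpf), 43 (BAA, PYR, 24 hpf) and interactions of 6 (BAA) and 26 (DBT). A fixed slide block gave 9 for BAA at 24 hpf. A random slide block gave 101 for DBT at 24 hpf, interactions of 1 (BAA), 48 (DBT) and 1 (PYR), and the cardiac list in 0 comparisons. The strict filter gave 17 (BAA, 24 hpf) and 6 (PYR, 48 hpf) against DMSO and interactions of 1 (BAA) and 20 (DBT); outlier spots kept gave 16 for BAA at 24 hpf, and the variance trend 1 for the BAA interaction. Without a filter the BAA and DBT correlation at 24 hpf was 0.0312, and a fold of at least 1.5 left 7528 probes between DMSO ages.

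With an estimated correlation the cholesterol list was called in 1 comparison in place of 4, and the cardiac, erythroid, fatty acid, inflammation, lens and retina, myeloid, neural, p53, pigment, muscle and vascular lists in 0. With the mean of a gene's probes the lists called were cardiac in 0, p53 in 0, erythroid in 1, other xenobiotic metabolism in 1 in place of 0, and vascular in 2 in place of 1.

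With each array left out, the counts against DMSO ran from 9 to 541 (BAA), 2 to 104 (DBT) and 0 to 1 (PYR) at 24 hpf and from 171 to 1429 (DBT) and 3 to 10 (PYR) at 48 hpf. At 24 hpf they were 385 to 2396 (BAA, DBT) and 6 to 528 (BAA, PYR), and at 48 hpf 129 to 1249 (BAA, DBT), 28 to 49 (BAA, PYR) and 20 to 261 (DBT, PYR). Interactions ran from 1 to 106 (BAA), 4 to 78 (DBT) and 0 to 2 (PYR). The BAA and DBT correlation at 24 hpf ran from -0.0743 to 0.133, and the adjusted p of the erythroid list with DBT at 24 hpf from 0.000982 to 0.872. BAA at 48 hpf (21 to 36) and the DMSO ages (10285 to 11254) stayed within 1.5 times.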

Other observations

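List tests between DMSO ages, between compounds and of BAA effects by age, and stage scores other than BAA at 24 hpf, were added after the data were seen.

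Development from 24 to 48 hpf in DMSO embryos moved many of the fixed lists. Cell cycle and replication genes fell: 23 of 26 members were lower and 0 higher, with a mean log2 change of -0.91 (camera adjusted p = 1.05e-12, and adjusted p = 0.00751 with an estimated correlation). Lens and retina genes had 26 of 38 members higher and 4 lower (mean 2.19, adjusted p = 3.62e-13, and adjusted p = 0.0802 with an estimated correlation). Neural genes had 22 higher and 4 lower of 39 (adjusted p = 7.96e-07, and adjusted p = 0.12 with an estimated correlation) and skeletal muscle genes 21 and 6 of 41 (adjusted p = 0.000388, and adjusted p = 0.365 with an estimated correlation). Cartilage, bone and matrix genes had 22 higher and 3 lower of 41 (adjusted p = 8.63e-06, and adjusted p = 0.0917 with an estimated correlation), liver and yolk syncytial layer genes 17 and 2 of 33 (adjusted p = 0.000156, and adjusted p = 0.106 with an estimated correlation) and glycolysis and hypoxia genes 15 and 2 of 29 (adjusted p = 0.00225, and adjusted p = 0.0917 with an estimated correlation). Myeloid leukocyte markers had 10 of 19 higher and 0 lower and inflammation genes 14 and 2 of 33, both at adjusted p = 0.365 with an estimated correlation (0.00425 and 0.00101 at the preset). The AHR-responsive genes had 5 of 14 members higher with age in DMSO, but were not called as a list (adjusted p = 0.24).

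Between compounds, the AHR-responsive genes were higher with BAA than with DBT at 24 hpf (4 of 14 members, adjusted p = 0.00822 with an estimated correlation) and at 48 hpf (6 of 14, adjusted p = 3.24e-06 with an estimated correlation). At 24 hpf the lens and retina genes had 12 of 38 members higher with BAA than DBT (adjusted p = 8.7e-09, and adjusted p = 0.281 with an estimated correlation). At 48 hpf the inflammation genes had 7 of 33 members lower and 2 higher with BAA than DBT (adjusted p = 0.000281, and adjusted p = 0.366 with an estimated correlation). Cholesterol biosynthesis genes were higher with DBT than PYR at 48 hpf, with 2 of 24 called (adjusted p = 2.76e-07, and adjusted p = 0.299 with an estimated correlation). The BAA effect on lens and retina genes was lower at 48 than at 24 hpf as a list (adjusted p = 3.24e-05, and 0.417 with an estimated correlation), with 0 members called by limma.

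In the other 5 comparisons with DMSO the stage score did not pass an exact two-sided permutation test with n = 4 each. Compound minus DMSO was 0.0158 for BAA at 48 hpf (exact p = 0.629), -0.0698 for DBT at 24 hpf (exact p = 0.2) and -0.0951 for DBT at 48 hpf (exact p = 0.0571). For PYR it was -0.00968 at 24 hpf (exact p = 0.914) and -0.0390 at 48 hpf (exact p = 0.171).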
